A study of Zea mays with 48 samples.

How the data were processed

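Leaf RNA of maize was sequenced in 48 libraries, 3 for each of 16 groups given by genotype (W22 or bzip60-2), stage (V4 or V5) and maximum daily temperature (31, 33, 35 or 37 °C). Per the labels' protocols, poly(A) RNA was isolated with oligo(dT) beads, and libraries and sequencing were done by BGI. Per the labels, 4 conditions were run in 8 chambers with a pair of chambers for each, and samples came from different plants in both chambers. The series text says that each replicate came from several plants, while the extract protocol describes a sample from each of 3 plants. Whether a library holds a single plant or a pool is therefore not settled.

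The FPKM values were made by the authors before they were deposited, and per the file headers each column holds the FPKM of 1 library, with values given to 2 decimals. Per the submitters' processing notes, HISAT2 2.0.4, HISAT, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 were used; the notes do not say for which step. The genome build and annotation are not given in the sources used here. Counts were not used here, so no count model was fitted, and how reads shared between near-identical genes were divided is not known. Of 33309 genes, 1189 share their values in all libraries with another gene.

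Computed here from the deposited FPKM were log2(FPKM + 1) values, which were used on the log2 scale throughout. Genes with an FPKM of at least 1 in at least 3 libraries were kept (22794 of 33309). A linear model with 16 group means was fitted to the 48 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), and p values were adjusted by the Benjamini-Hochberg method over all genes, two-sided, with a threshold of 0.05. Contrasts were each temperature against 31 °C within genotype and stage, the genotypes at each temperature and averaged over 4 temperatures, the difference between genotypes in the response to temperature, and the stages within genotype. Moderated F tests covered the 3 temperature contrasts at once. Changes of at least 2-fold are a log2 change of 1 or more in either direction. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

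The design, the contrasts, the rule for named genes, 22 gene lists and the alternatives of filter, pseudocount, normalization, array weights, replicate block, smaller models and left-out libraries were fixed before the data were examined. The lists could not be tested, because the 30432 nuclear identifiers of the table had 0 matches in the reference table of symbols, and the genes that were to be named first, bZIP60 among them, were not analysed here. The rule then names at most 2 identifiers with the largest rise and 2 with the largest fall per contrast, among genes past the threshold, with a mean of at least 5 FPKM in the highest group compared. These genes also had to move the same way throughout: every replicate of 1 group above every replicate of the other at 37 against 31 °C, or the same sign at all 4 temperatures between genotypes. For differences between genotypes in the response to temperature, no such condition was set. All 211 organelle locus tags were found in that table. Those whose symbol is a gene name, not the label of an open reading frame, met the rule's condition of a descriptive name and are named by it up to 6 in each direction. Of the genes that met the rule, 2 are not reported here. Organelle genes quoted beyond these, as examples of their groups, were chosen after their values were seen.

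Added after the data were seen were the organelle groups, tested with camera, a fit to the 16 group means, and the term for the library sets. The groups are the 29 plastid and 21 mitochondrial genes with such names, of 31 and 65 tested; left out were 44 unnamed mitochondrial reading frames and 2 plastid genes with values identical to another. They were tested at a preset correlation between genes and again with the correlation estimated, with adjustment over 20 tests. Poly(A) selection removes most organelle RNA. Some of the plastid genes, such as clpP and rpl16, and of the mitochondrial genes, such as nad4L and rps7, were listed at 0 in some libraries. Several mitochondrial genes lay near the floor, with means of 0.324 FPKM for nad4L, 0.403 for ccmC and 0.554 for cob. The organelle values therefore carry more doubt than those of nuclear genes. Group means were fitted because the replicates of a group were so alike that p values from libraries measure the spread between these samples alone. In that fit, 8 pairs of group means gave the genotype difference, and a straight line over temperature with a level for each series gave the slope. The library sets were divided at 10 FPKM of Zm00001d033132, and a term for them was added to the model.

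Size factors (the median of ratios to the geometric mean over genes), computed as an alternative scaling, ran from 0.752 to 1.31. They rose from W22 V4 (0.758 to 0.872) to bzip60-2 V4 (0.888 to 1.06), W22 V5 (0.957 to 1.21) and bzip60-2 V5 (1.18 to 1.30), so splits into higher and lower genes are given with and without scaling. The depth in reads is unknown, and no counting interval could be given. The table's lowest values were used to estimate the depth of libraries relative to each other.

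The scripts were tested on simulated data with known changes in 200 of 22794 genes. The changes had random signs and the noise was independent between genes, whereas the real tests from libraries called 25.6% to 82.2% of genes. The shares below therefore do not describe tests with so many changes or with a shift of most genes. At log2 changes of 0.25, 0.5, 1 and 2, the right call was made for 14, 68, 92 and 100% of changed genes in a contrast of 37 against 31 °C, where 7.43% of calls were unchanged genes. For a difference in response between genotypes the shares were 8, 38, 82 and 94% (1.77%), for 8 pairs of group means 16, 56, 96 and 100% (6.29%), for the slope 0, 18, 80 and 96% (5.83%), and for the set term 6, 34, 80 and 96% (4.42%). Simulated genes that differed between the library sets alone were called in 64.5% without the set term and 0% with it, in the contrast of 37 against 31 °C in bzip60-2 at V4.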

Results

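Leaf transcripts were measured by RNA-seq in maize (Zea mays) of the inbred line W22 and in the bzip60-2 mutant, grown in chambers whose maximum daily temperature was 31, 33, 35 or 37 °C. bZIP60 is a transcription factor of the unfolded protein response, the signalling that raises protein folding capacity in the endoplasmic reticulum, and the series asks how this response is tied to the heat response. The newest fully expanded leaf was sampled at its middle at V4, when the collar of leaf 4 is visible (20 days after germination), and at V5 (27 days). The 48 libraries form 16 groups of 3, 1 group for each combination of genotype, stage and temperature. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). They summed to between 869999 and 941520 per library, with 24520 to 26641 genes above 0. The absolute depth is unknown. From the smallest steps between low values, the depth of the libraries relative to each other was estimated at 0.771 to 1.07, over 143 to 304 genes per library. Nuclear genes are given below by their identifiers, because no source used here pairs these identifiers with names, and the transcript of the mutated gene was therefore not analysed here.

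Stage, temperature and genotype all separated the libraries, in values without size-factor scaling. Of the total variance of log2(FPKM + 1) over 22794 genes, 89.0% lay between the 16 groups, with 31.0% between stages, 20.0% between temperatures and 16.0% between genotypes. The first principal component (42.1% of the variance) placed W22 at V4 lowest and, as a series, bzip60-2 at V5 highest. W22 at V5 and 33 °C, with a group mean of 49.4, lay above bzip60-2 at V5 and 37 °C (40.6). Their mean size factors were 1.21 and 1.18. This component broadly rose with the size factor of the groups. The factor was 0.758 in W22 V4 at 33 °C, placed at -76.3, and 1.30 in bzip60-2 V5 at 33 °C, placed at 70.2. The components were not computed after scaling, so the order on the first cannot be told apart from the scale of the libraries. The second component (12.0%) followed temperature in all 4 series of genotype and stage. The median coefficient of variation between the 3 libraries of a group was 2.29% to 3.38% in 15 groups, over 1350 abundant genes, and 5.72% in W22 at V4 and 37 °C. The share of all FPKM held by the 100 most abundant genes of a group was 33.2% to 38.5% in W22 at V4, 30.7% to 36.4% in bzip60-2 at V4, 25.9% to 33.7% in W22 at V5 and 24.3% to 27.6% in bzip60-2 at V5.

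**Figure D1:**
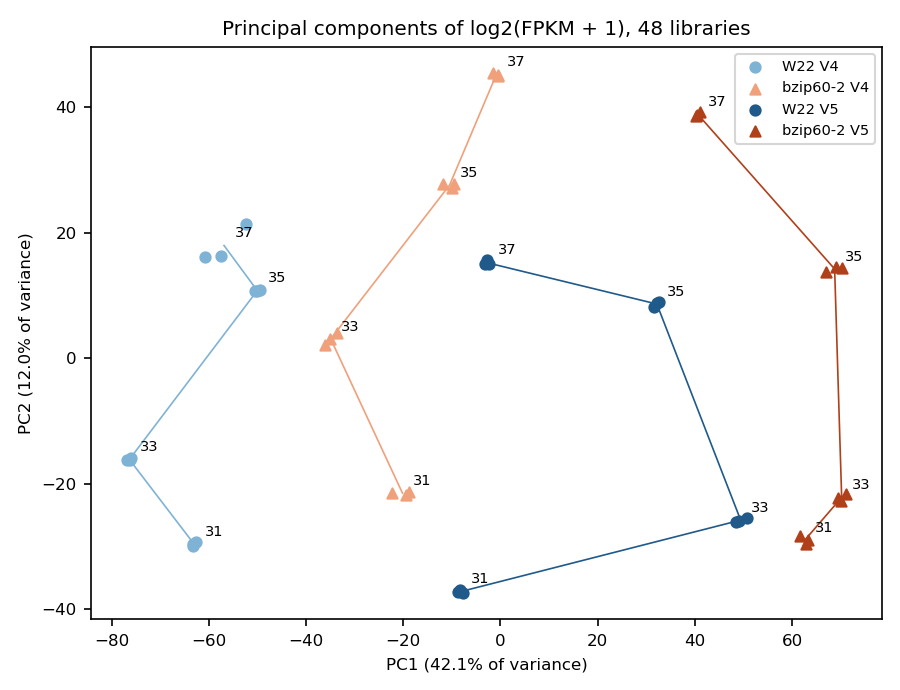
Principal components of log2(FPKM + 1), with PC1 (42.1% of the variance) on the x axis and PC2 (12.0%) on the y axis. Each point is 1 of 48 libraries, lines join the group means of a series over 31, 33, 35 and 37 °C, and the series lie from W22 V4 on the left (group means from -76.3 to -50.0 on PC1) to bzip60-2 V5 on the right (from 40.6 to 70.2).

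The libraries also fell into 2 sets that the labels do not name. Transcript Zm00001d033132 was below 10 FPKM in 14 libraries and above it in 34. The 14 libraries are those of W22 at V4, except replicate 3 at 37 °C, and those of bzip60-2 at V4 and 31 °C. Within W22 at V4 and 37 °C, Zm00001d033132 measured 0.33, 1.29 and 172 FPKM in replicates 1, 2 and 3, and replicate 3 differed at least 2-fold from the mean of its partners in 135 genes. The numbers were 61 and 59 for replicates 1 and 2, whose partners include replicate 3, and at most 30 for any library of the other 15 groups. By the model 1164 genes differed between replicate 3 and these partners (589 higher and 575 lower in replicate 3, 148 of them at least 2-fold). This compares 1 library with 2, with the error taken from the spread within all groups. Counts of genes for comparisons that cross the sets are given below also from a model that holds a term for the sets, added after the data were seen. The term is estimated from these 3 libraries, the only group that holds both sets, so it is imprecise.

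At 37 against 31 °C, Zm00001d024903 rose in W22 leaves from 1.26 ± 0.465 to 52.5 ± 5.61 FPKM at V4 (mean ± SD, n = 3) and from 6.79 ± 0.259 to 255 ± 1.76 at V5. The log2 changes were 4.58 (SE 0.0777, adjusted p = 4.99e-34) and 5.04 (SE 0.0777, adjusted p = 1.16e-35). Zm00001d043968 rose from 7.99 ± 3.24 to 203 ± 10.4 at V4, and Zm00001d004243 from 0.310 ± 0.132 to 31.6 ± 0.728 at V5. Zm00001d024522 fell from 26.7 ± 2.75 to 0.677 ± 0.171 at V4. There Zm00001d043374 fell from 51.5 ± 0.792 to 3.21 ± 0.200, and Zm00001d039524 fell from 50.8 ± 2.95 to 3.12 ± 0.401 at V5. Among the organelle genes, matK, the plastid intron maturase, rose from 4.80 ± 0.388 to 14.5 ± 0.978 at V4 and from 3.32 ± 0.405 to 11.7 ± 2.17 at V5. The transcript of ycf3, whose product assists the assembly of photosystem I, fell from 54.5 ± 4.51 to 20.8 ± 4.51 at V4 and from 83.2 ± 2.40 to 30.5 ± 2.98 at V5.

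Of 21 named mitochondrial genes measured in W22, 12 rose at 37 °C at V4 and 14 at V5, and 0 fell at either stage (camera adjusted p = 0.00132 and 2.08e-05). At V5 the risers included the cytochrome c oxidase subunits cox3, with a log2 change of 1.77 (SE 0.207, adjusted p = 3.91e-09), and cox2, with 1.36 (SE 0.156, adjusted p = 2.49e-09). They also included the ATP synthase subunit atp4 (1.29) and the ribosomal protein gene rps2B (1.24). At V4 they included rps12 (1.46, SE 0.166, adjusted p = 1.93e-09) and nad3, a subunit of respiratory complex I (0.93, SE 0.177, adjusted p = 3.53e-05). With an estimated correlation between genes, the camera adjusted p was 0.0218 at V4 and 0.00487 at V5. Of 29 named plastid genes, 12 rose and 9 fell at V4, and 10 rose and 4 fell at V5 (camera adjusted p = 0.666 and 0.155). The plastid ATP synthase subunits atpF and atpB rose at V4 (0.82 and 0.70), as did the ribosomal protein gene rps3 (0.75), while rpl2 (-0.84) and the photosystem I core gene psaB (-0.53) fell. At V5, atpF rose (0.94), and atpI (-0.50) and psaB (-0.44) fell. Both organelle groups were formed after the gene names were seen, and their members were read from poly(A)-selected RNA. Several mitochondrial members, such as nad4L and cob, lay near the floor of the values. A further 44 mitochondrial open reading frames without a gene name were tested outside the group: 4 rose and 3 fell at V4, and 14 rose and 0 fell at V5.

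In all, 10560 of 22794 genes passed the threshold at V4 (6072 higher and 4488 lower) and 10084 at V5 (4992 and 5092). At least 2-fold changes numbered 481 higher and 589 lower at V4 and 465 and 554 at V5, and the V4 numbers became 465 and 766 when libraries were scaled by size factors. The calls for the plastid genes atpH at V4 (-0.82, SE 0.299, adjusted p = 0.0225) and psaA at V5 (-0.39, SE 0.127, adjusted p = 0.0125) were lost when single libraries were left out. For atpH these were replicate 2 or 3 at 31 °C or replicate 1 at 37 °C (highest adjusted p = 0.124). For psaA they were replicate 3 at 31 °C or replicate 1 or 3 at 37 °C (0.0980). Zm00001d033133, with a log2 change of -3.62 (SE 1.28, adjusted p = 0.0197) at V5, was unstable between libraries and measured 192, 212 and 532 FPKM at 31 °C and 10.4, 53.1 and 18.1 at 37 °C. Its call was lost without replicate 3 at 31 °C or replicate 1 or 3 at 37 °C (highest adjusted p = 0.0832). Without replicate 3 of W22 at V4 and 37 °C, 9794 genes passed at V4.

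In bzip60-2 leaves the same comparison gave 3.47 ± 0.0404 and 176 ± 4.07 FPKM for Zm00001d024903 at V4, and 17.7 ± 0.539 and 303 ± 3.66 at V5. The log2 changes were 5.31 (SE 0.0777, adjusted p = 2.36e-36) and 4.03 (SE 0.0777, adjusted p = 5.15e-33). Zm00001d004243 rose from 0.497 ± 0.264 to 68.5 ± 1.23 at V4 and from 1.12 ± 0.100 to 53.4 ± 3.06 at V5. Zm00001d043968, which rose at both stages in W22, did not pass in the mutant, with log2 changes of 0.20 (SE 0.223, adjusted p = 0.464) at V4 and 0.31 (SE 0.223, adjusted p = 0.257) at V5. The difference between the genotypes in its response was -4.37 (adjusted p = 9.95e-14) at V4 and -0.79 (adjusted p = 0.0489) at V5. The plastid genes matK (1.70) and atpF (1.18) rose at V5, and ycf3 fell (-1.56). Of the 21 mitochondrial genes 16 rose at V4 and 0 fell (camera adjusted p = 0.00422, and 0.0241 with an estimated correlation), led by cox3 (1.93, SE 0.207, adjusted p = 3.58e-10) and cox2 (1.49, SE 0.156, adjusted p = 2.06e-10). Of the 44 open reading frames outside the group, 9 rose and 6 fell at V4. At V5, 6 genes of the group rose and 4 fell (camera adjusted p = 0.463), with cox3 higher (0.72, SE 0.207, adjusted p = 0.00349) and rps12 and nad3 lower (-0.84 and -1.03).

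In this comparison 12590 genes passed at V4 (7643 higher and 4947 lower) and 12225 at V5 (4751 and 7474), of which 855 and 841 at V4 and 667 and 1294 at V5 changed at least 2-fold. Size-factor scaling changed the splits to 5887 higher and 6238 lower at V4 and to 5853 and 5694 at V5, and the 2-fold split at V4 to 664 and 996. The V4 comparison crosses the library sets. With the set term 7019 genes passed, 1104 of the 1696 genes called at least 2-fold kept that call, and 7 mitochondrial genes rose and 0 fell. In that model cox3 kept its call (1.43, adjusted p = 0.00233), as did cox2, while nad3 went from 0.76 (SE 0.177) to 0.05 (SE 0.290) and lost its call (adjusted p = 0.926). Of 29 plastid genes, 13 rose and 5 fell at V5 (camera adjusted p = 0.0159, and 0.290 with an estimated correlation).

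**Figure D2:**
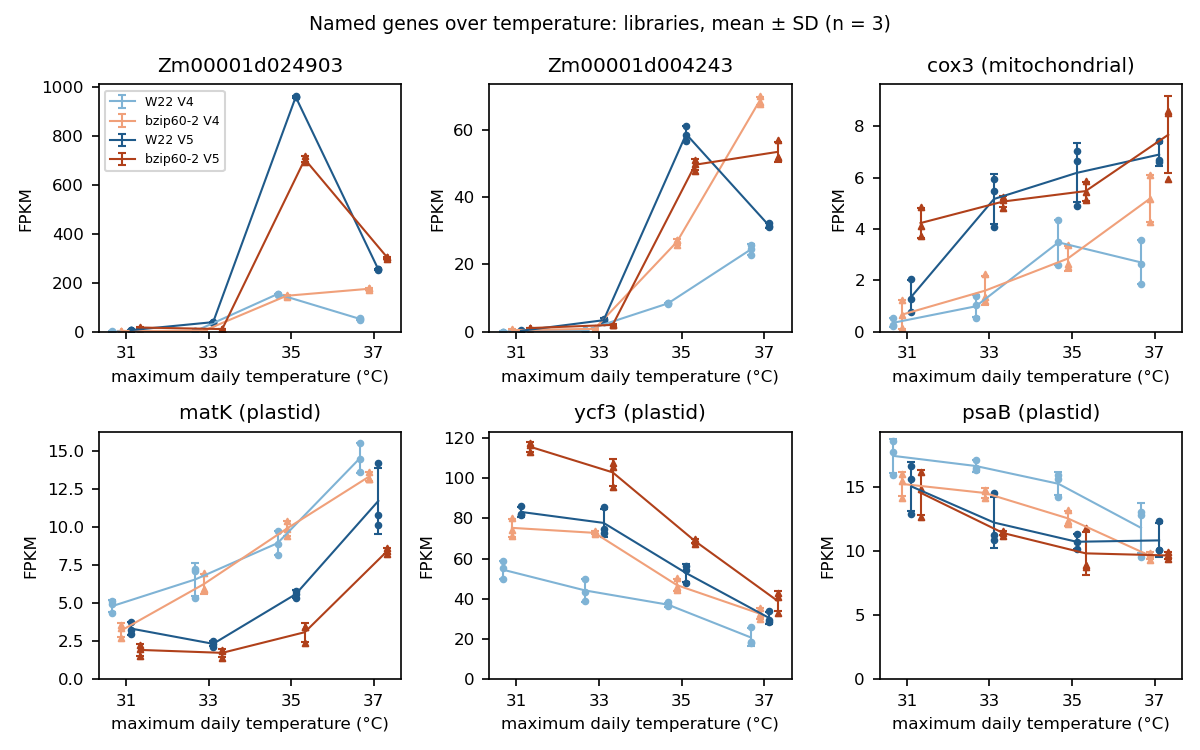
FPKM of 6 genes (y axes) against maximum daily temperature in °C (x axes). Points are libraries, lines join group means and bars are SD over 3 libraries; ycf3 falls with temperature in all 4 series, and Zm00001d024903 is highest at 35 °C in W22 V4, W22 V5 and bzip60-2 V5.

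Across the 4 series, 186 genes changed at least 2-fold in 1 direction in each at 37 against 31 °C. Of these 85 rose, where independent lists would share 0.0108 higher genes and 0.0300 lower ones. A straight line over the 4 temperatures, fitted to the 16 group means with a level for each series, passed the threshold for 3601 genes (1960 rising and 1641 falling), a result added after the replicate spread was seen. From 31 to 37 °C the fitted log2 changes were 5.82 (adjusted p = 0.00145) for Zm00001d024903 and 5.46 (adjusted p = 7.36e-05) for Zm00001d004243. They were -3.48 (adjusted p = 0.00649) for Zm00001d011183 and -3.46 (adjusted p = 0.000122) for Zm00001d037383. Among organelle genes they were 1.64 (adjusted p = 0.000177) for matK, 1.47 (adjusted p = 0.000760) for cox3 and 1.23 (adjusted p = 0.000438) for cox2, and they were -1.39 (adjusted p = 4.3e-05) for ycf3 and -0.53 (adjusted p = 0.00158) for psaB. For Zm00001d024903 the fitted change was above the observed change at 37 against 31 °C in every series (at most 5.31, in bzip60-2 V4). By family, 6 of 12 respiratory chain and ATP synthase genes and 4 of 6 ribosomal protein genes of the mitochondrion rose and 0 fell, and of the plastid ATP synthase genes 3 of 5 rose and 2 fell. The calls for atp8 and cox1, a subunit of ATP synthase and of cytochrome c oxidase, were lost without W22 V4, bzip60-2 V4 or W22 V5 at 31 °C or bzip60-2 V4 at 37 °C (highest adjusted p = 0.0707 and 0.0642). That for atp8 was also lost without W22 V4 at 37 °C or bzip60-2 V5 at 31 or 37 °C. In the limma fit to group means no gene was called for a difference in slope between genotypes (0 called, 774 genes at an unadjusted p under 0.05, where chance gives 1140). Between stages 1 gene was called (2078 unadjusted). A straight line left 43.3% to 70.6% of the temperature sum of squares of a series outside it. The fit is thus insensitive, and its lack of calls does not show equal responses. Leaving out 1 group moved the number of slopes called to between 2418 (without bzip60-2 at V4 and 31 °C) and 4450 (without W22 at V5 and 33 °C).

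At 35 °C, Zm00001d024903 reached 154 ± 1.67 FPKM in W22 at V4 and 959.8 ± 2.58 at V5, above its level at 37 °C, and in bzip60-2 at V5 it reached 705 ± 12.3. Zm00001d011183 stood at 303 ± 9.96, 1123 ± 13.96, 81.8 ± 2.70 and 42.5 ± 2.80 FPKM at the 4 rising temperatures in W22 at V5, and at 291 ± 6.58, 1532 ± 24.8, 139.7 ± 4.35 and 14.6 ± 0.299 in bzip60-2. Among genes changed at least 2-fold at 37 °C, the 4 group means followed the temperature order in 44.95% in W22 V4, 51.7% in bzip60-2 V4, 24.04% in W22 V5 and 41.8% in bzip60-2 V5. These genes were chosen by their change at 37 °C, which itself favours this order. At 33 against 31 °C, 80 genes rose and 389 fell at least 2-fold in W22 V4, 231 and 734 in bzip60-2 V4, 1530 and 460 in W22 V5, and 348 and 623 in bzip60-2 V5. At 35 °C the numbers were 499 and 464, 531 and 507, 1137 and 479, and 365 and 549 in the same order. Size-factor scaling changed the numbers at 33 °C to 146 and 392 in W22 V4, 345 and 602 in bzip60-2 V4, and 648 and 813 in W22 V5. At 35 °C it changed them to 431 and 623 in W22 V4 and 910 and 679 in W22 V5. The median log2 change of all genes at 33 °C in W22 V5 was 0.30 as deposited and 0.03 after scaling. In bzip60-2 V4 10318 genes passed at 33 °C and 10417 at 35 °C at any size of change, and 4508 and 4743 with the set term. By the F test over temperatures 15040 genes passed in W22 V4, 16452 in bzip60-2 V4, 18470 in W22 V5 and 16591 in bzip60-2 V5, and with the set term 14588 in W22 V4 and 13842 in bzip60-2 V4. Each temperature was run in its own pair of chambers, so temperature and chamber pair cannot be told apart.

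**Figure D3:**
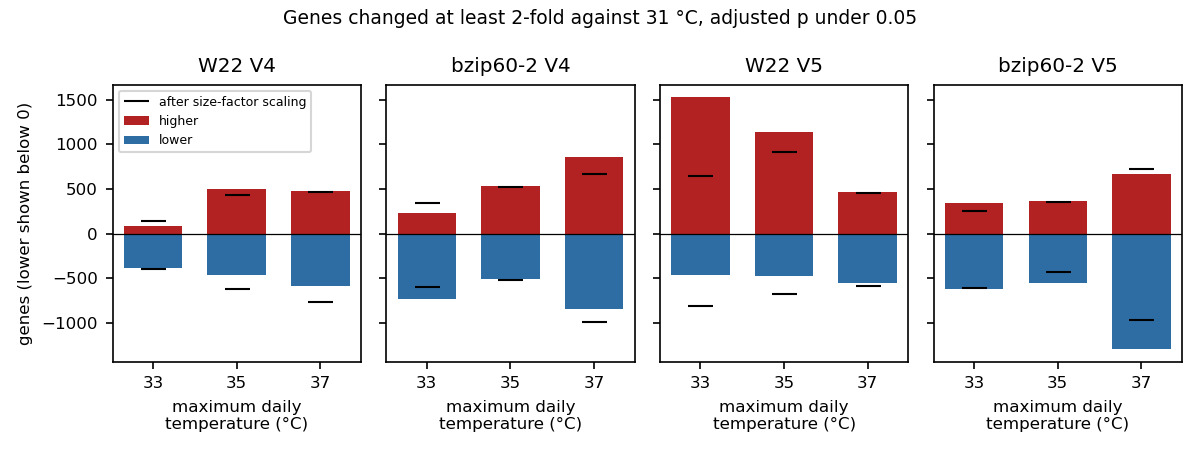
Number of genes changed at least 2-fold with an adjusted p under 0.05 (y axis, genes lower drawn below 0) at 33, 35 and 37 against 31 °C (x axis) in the 4 series. Bars are values as deposited and black lines the numbers after size-factor scaling; in W22 V5 at 33 °C scaling lowers the genes higher from 1530 to 648 and raises the genes lower from 460 to 813.

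Between the genotypes, Zm00001d039684 averaged 114 FPKM over the 8 groups of bzip60-2 and 0.485 over those of W22, a log2 difference of 6.23 (SE 0.122, adjusted p = 5.96e-10). Zm00001d040787 averaged 203 and 7.99 (4.77, SE 0.413, adjusted p = 3.28e-05). Zm00001d045322 averaged 0.0104 FPKM in the mutant and 12.8 in W22 (-3.74, SE 0.103, adjusted p = 6.14e-09), and was listed at 0 in 7 of the 8 mutant groups. Zm00001d046599 was lower in the mutant, at 10.2 against 85.7 (-2.96, SE 0.0698, adjusted p = 2.23e-09). Zm00001d007773 was higher in the mutant at V5 (4.37, SE 0.0531, adjusted p = 5.84e-40), and Zm00001d051194 was lower there (-3.44, SE 0.0487, adjusted p = 1.01e-37). The plastid gene ycf3 was higher in the mutant (0.47, SE 0.0595, adjusted p = 0.000387) and atpF lower (-0.33, SE 0.0688, adjusted p = 0.00396), over 8 pairs of group means.

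At V5, where both genotypes belong to 1 library set, 2 of 29 plastid genes were higher in the mutant and 13 lower (camera adjusted p = 3.95e-07, and 0.0240 with an estimated correlation). The lower genes included rps3 (-0.51), matK (-0.49), atpF (-0.44), rpl22 (-0.38), atpB (-0.36) and ndhC (-0.23), a subunit of the plastid NDH complex. Averaged over the temperatures, 17 of the 21 mitochondrial genes were higher and 0 lower at V5. Among them were nad9 at 0.84 (SE 0.0985, adjusted p = 1.44e-09), atp4 at 0.53 and rps7 at 0.52. The calls at single temperatures lay mostly at 31 °C. In the model with the set term, 19 were higher at 31 °C, 3 at 33 °C, 3 at 35 °C and 1 at 37 °C, and 0 were lower. In the average, the group did not stand out from other genes (camera adjusted p = 0.476). The median of all genes was itself 0.20 higher in the mutant at V5 and 0.19 higher at V4, and 0.00 and -0.00 after size-factor scaling. After scaling 8 mitochondrial genes were higher and 0 lower at V5 (camera adjusted p = 0.0332), and 2 plastid genes were higher and 23 lower. The calls for rps2B (0.38) and rps13 (0.31) at V5 were lost after scaling (adjusted p = 0.104 and 0.446). That for rps13 was also lost when single libraries were left out (0.0524 to 0.0930). In W22 these were replicates 2 and 3 at 31 °C, 1 and 3 at 33 °C, 2 and 3 at 35 °C and 3 at 37 °C, and in the mutant 1 and 2 at 31 °C, 1 and 2 at 33 °C, 2 and 3 at 35 °C and 1 and 3 at 37 °C.

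Over the 4 temperatures 16096 genes differed between genotypes at V4 (13321 higher in the mutant and 2775 lower) and 16842 at V5 (14228 and 2614). With group means in place of libraries as the replicates, 5904 genes differed at V4 and 1704 at V5. Of the genes called from libraries, 468 and 99 at V4 and 372 and 145 at V5 differed at least 2-fold. Size-factor scaling made the splits 6483 higher and 6969 lower at V4 and 5501 and 6346 at V5, and the 2-fold splits 314 and 189 at V4 and 224 and 226 at V5. At 31, 33, 35 and 37 °C, 11337, 9846, 10833 and 13356 genes differed at V4 and 15401, 7414, 10517 and 12117 at V5. With the set term the V4 numbers were 11509, 3865, 4849 and 10226, and quantile normalization gave 7509 at 31 °C. Of the genes at least 2-fold apart, 223 were higher at both stages, where independent lists would share 7.64, and 49 were lower at both (0.630). Across 8 pairs of group means, a result added after the replicate spread was seen, 11035 genes differed (9946 higher and 1089 lower), 5475 after scaling (2493 and 2982), and 5929 over the 5 pairs within a set. At V4 only the 31 °C groups lie within 1 library set, and 584 genes were at least 2-fold higher and 118 lower there (372 and 231 after scaling). With the set term 9421 genes differed over temperatures at V4. In that model ycf3 went from 0.54 (SE 0.0491) to 0.21 (SE 0.0924) and lost its call (adjusted p = 0.0689) as it shrank. The calls for atpH, from -0.49 (SE 0.149) to -0.69 (SE 0.336), and atpB, from -0.24 (SE 0.0571) to -0.20 (SE 0.129), were lost to the larger error (adjusted p = 0.100 and 0.221). Those for atpF (from -0.21 to -0.35) and psaB (from -0.22 to -0.36) were kept. At V4, 5 plastid genes were higher and 11 lower (camera adjusted p = 0.000334, and 0.0809 with an estimated correlation), 4 and 22 after size-factor scaling, and 0 and 9 with the set term. Of the mitochondrial genes 7 were higher and 0 lower at V4, where camera placed the group below the other genes (adjusted p = 0.4995) although its median difference was 0.17, and with the set term 1 was higher and 0 lower. Of the 44 open reading frames outside the group, 0 were higher and 3 lower at V4, and 26 were higher and 2 lower at V5. The V4 call for rpl22 (-0.16, SE 0.0730, adjusted p = 0.0472) was lost without single libraries (highest adjusted p = 0.124). In W22 these were replicates 1 and 2 at 31 °C, 3 at 33 °C, 2 and 3 at 35 °C and 1 and 3 at 37 °C, and in the mutant 2 and 3 at 31 °C, 2 and 3 at 33 °C, 1 and 3 at 35 °C and all 3 at 37 °C.

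The response to 37 °C differed between the genotypes at V5 for nad3, with an interaction of -1.87 (SE 0.251, adjusted p = 1.23e-07) on the log2 scale, and rps12 (-1.78, SE 0.234, adjusted p = 8.13e-08), both lower in the mutant. The interactions of nad9 (-1.33), cox3 (-1.05) and atp4 (-0.98) had the same sign. Summed over the 21 mitochondrial genes, W22 stood at 53.7 ± 4.32 FPKM at 31 °C and 123.2 ± 1.58 at 37 °C, and bzip60-2 at 152 ± 5.67 and 125 ± 1.82 (mean ± SD, n = 3). Without rps12 the sums were 31.98 ± 3.19 and 80.5 ± 3.03 in W22 and 91.0 ± 2.66 and 91.4 ± 3.92 in bzip60-2, so without this gene the sum did not fall in the mutant. Of these genes 12 had a lower response in the mutant and 0 a higher one (camera adjusted p = 0.00476, and 0.0241 with an estimated correlation), and of the 44 open reading frames 10 and 0. Among nuclear genes, Zm00001d033846 went from 42.1 ± 3.10 to 48.1 ± 5.92 FPKM in W22 and from 3.76 ± 2.30 to 88.7 ± 8.40 in the mutant. Zm00001d037513 went from 78.7 ± 3.14 to 16.6 ± 0.887 and from 7.00 ± 0.233 to 29.4 ± 1.04. Zm00001d048774 went from 47.5 ± 3.78 to 0.163 ± 0.0709 in the mutant and from 1.34 ± 0.133 to 0.203 ± 0.177 in W22. Zm00001d024522 went from 126 ± 6.88 to 7.23 ± 1.08 in the mutant and from 29.7 ± 2.87 to 37.5 ± 1.15 in W22.

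**Figure D4:**
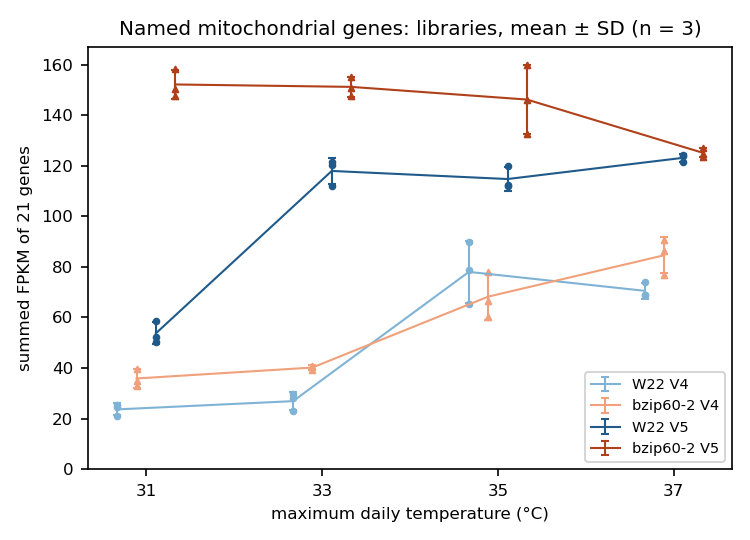
Summed FPKM of the 21 named mitochondrial genes (y axis) against maximum daily temperature in °C (x axis). Points are libraries, lines join group means and bars are SD over 3 libraries; bzip60-2 V5 is at 152 at 31 °C and 125 at 37 °C, and the other 3 series are higher at 37 than at 31 °C.

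In all, 7791 genes differed in their response to 37 °C at V5 (2848 higher in the mutant and 4943 lower), and 3824 higher and 3208 lower after size-factor scaling. Of the plastid genes, rpl22 (0.64, SE 0.206, adjusted p = 0.0141) and ndhK (0.22, SE 0.0824, adjusted p = 0.0390) had a higher response in the mutant, and each call was lost on leaving out single libraries. These were replicate 3 of W22 at 37 °C or replicate 2 of bzip60-2 at 31 °C for rpl22 (highest adjusted p = 0.0678). For ndhK they were replicate 3 at 31 °C and replicates 1 and 3 at 37 °C in W22, and replicates 1 and 2 at either temperature in bzip60-2 (0.113). The plastid protease gene clpP, with -4.38 (SE 0.392, adjusted p = 9.09e-12), measured 17.7, 18.5 and 19.9 FPKM in bzip60-2 at 31 °C and was listed at 0 in all 3 libraries at 37 °C. In W22 it was listed at 0 at 31 °C, so its value is uncertain.

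At V4 the response also differed for Zm00001d011515, which went from 1.53 ± 0.265 to 51.8 ± 6.25 FPKM in W22 and from 13.9 ± 5.60 to 5.27 ± 1.03 in the mutant (-5.57, SE 0.400, adjusted p = 7.96e-14). Zm00001d011461 went from 4.97 ± 3.10 to 56.9 ± 10.7 and from 23.9 ± 4.47 to 11.6 ± 4.57 (-4.45, SE 0.323, adjusted p = 1.05e-13). The mitochondrial gene nad9 responded more in the mutant (0.85, SE 0.279, adjusted p = 0.0196). The call was lost without replicate 3 of either genotype at 31 °C, replicate 1 of W22 at 37 °C, or replicate 1 or 2 of the mutant at 37 °C (highest adjusted p = 0.0773). In all 6324 genes passed at V4 (3477 higher and 2847 lower), with 2 mitochondrial genes higher and 0 lower (camera adjusted p = 0.880), and 6 plastid genes higher and 1 lower (0.633). After size-factor scaling 2 mitochondrial genes were higher and 2 lower. With the set term 4491 genes passed, and 541 of the 787 genes called at least 2-fold kept that call. In that model 1 plastid gene was higher and 3 lower, and 1 mitochondrial gene was higher and 0 lower.

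Some V4 interactions followed the library sets. Zm00001d033132 and Zm00001d033136, which have identical values, gave 4.27 (SE 1.11, adjusted p = 0.00322), and -0.15 with the set term (adjusted p = 0.885), though the first of these genes was used to divide the sets. For rpl16, with 4.34 (SE 0.786) and 1.92 (SE 0.677, adjusted p = 0.0402) with the term, the libraries of W22 at 37 °C were listed at 0, 4.11 and 26.9 FPKM. The interaction of rps3 went from 0.40 (SE 0.145) to 0.01 (SE 0.137, adjusted p = 0.979). That of rpl2 did not follow the sets: it went from 0.43 (SE 0.156) to 0.47 (SE 0.193), and its call was lost to the larger error (adjusted p = 0.0865). Both calls were also lost when single libraries were left out. For rpl2 these were replicates 1 and 2 at 31 °C and 1 and 3 at 37 °C in W22, and replicates 1 and 2 at either temperature in the mutant (up to 0.150). For rps3 they were replicates 2 and 3 at 31 °C and 1 and 2 at 37 °C in W22, and replicates 2 and 3 at either temperature in the mutant (up to 0.184). In bzip60-2 at 31 °C clpP measured 5.01, 17.1 and 6.60 FPKM, and at 37 °C it was listed at 0 in replicates 1 and 3 (-2.58, also with the set term). By the F test over temperatures, 11152 genes at V4 (9475 with the set term) and 13564 at V5 responded differently in the genotypes.

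At V5 against V4, transcripts of all 21 named mitochondrial genes were higher in both genotypes, and most plastid genes were lower. Mitochondrial nad9 was higher at V5 by 1.38 (SE 0.0985, adjusted p = 1.43e-15) on the log2 scale in W22 and by 1.81 (SE 0.0985, adjusted p = 4.83e-19) in bzip60-2, with 1.95 ± 0.498 FPKM at V4 and 4.79 ± 0.712 at V5 in W22 at 31 °C. The plastid genes matK and atpF were lower in W22 (-0.62 and -0.58) and in bzip60-2 (-0.99 and -0.80). Of 29 plastid genes 3 were higher and 18 lower in W22 (camera adjusted p = 3.95e-07), and 2 were higher and 20 lower in bzip60-2 (1.29e-08). With an estimated correlation these adjusted p values were 0.0240 and 0.0206. The mitochondrial group gave a camera adjusted p of 0.0290 in W22 (0.0809 with an estimated correlation) and 0.00476 in bzip60-2 (0.0241).

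Over the 4 temperatures 18586 genes differed between the stages in W22 (14978 higher at V5 and 3608 lower) and 18732 in bzip60-2 (15264 and 3468). With group means as the replicates the numbers were 6229 in W22 and 8859 in bzip60-2. From libraries and at least 2-fold apart, 1097 were higher and 323 lower in W22, and 975 and 381 in bzip60-2. The median of all genes was 0.29 higher at V5 in W22 and 0.30 in bzip60-2. After size-factor scaling, 8835 genes were higher and 7805 lower in W22 and 8394 and 7344 in bzip60-2. The 2-fold splits became 559 higher and 699 lower in W22 and 434 and 700 in bzip60-2. Of the genes at least 2-fold apart, 573 were higher in both genotypes and 207 lower, where independent lists would share 46.9 and 5.40. The comparison crosses the library sets at 31 °C in bzip60-2, where 17762 genes passed with the set term, and at every temperature in W22. In W22 11224 genes passed with the term, with 15 mitochondrial genes higher and 0 lower, and 0 plastid genes higher and 16 lower. In that model nad9 kept its call (1.56, adjusted p = 2.9e-05) and the mitochondrial group did not pass (camera adjusted p = 0.175). Stage and the age of the plants, 20 against 27 days, cannot be told apart.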

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

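Chosen after the result was seen were, in this part, the library-set term, the organelle groups, the splits with the genotype difference taken out, the tests of carry-over and of library scale for the mitochondrial genes, and the 3 tests on the library that stands apart. The genotypes differed in their response to temperature, by an interaction test in limma, for 11152 genes at V4 and 13564 at V5 over all temperatures, and for 6324 and 7791 at 37 against 31 °C. In other splits of the libraries the difference between genotypes enters the interaction, so these decide nothing: 4 of 100 splits at V4 and 2 of 100 at V5 gave as many genes over all temperatures (highest other 13990 and 13813), and 17 and 9 of 100 at 37 °C (14617 and 16351). With that difference taken out of the libraries first, 1 of 100 splits, the real one, gave as many genes in each test. A random assignment of the libraries is argued against by this measure. The highest others were then 4813 at V4 and 8591 at V5 over all temperatures, and 3646 and 4028 at 37 °C. This rests on libraries as the replicates: from group means the slopes over temperature differed between genotypes for 0 genes (774 at an unadjusted p under 0.05, where chance gives 1140). The slope fit tests a straight line alone and is insensitive, so its lack of calls does not show equal responses.

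At V4 the interaction at 37 °C was -5.57 for Zm00001d011515, -4.45 for Zm00001d011461, 4.27 for Zm00001d033132 and for Zm00001d033136, and 0.85 for mitochondrial nad9. Those of Zm00001d033132 and Zm00001d033136 followed the library sets, and the call for nad9 was lost without single libraries. The plastid genes gave 4.34 for rpl16, 0.43 for rpl2, 0.40 for rps3 and -2.58 for clpP. With the set term the value of rpl16 shrank and that of rps3 was lost. The calls for rpl2 and rps3 were also lost without single libraries. At V5, Zm00001d033846 gave 4.15, Zm00001d037513 4.11, Zm00001d048774 -4.41 and Zm00001d024522 -4.29. The plastid genes gave 0.64 for rpl22, 0.22 for ndhK and -4.38 for clpP. The calls for rpl22 and ndhK were lost without single libraries, and the value of clpP is uncertain. The mitochondrial genes gave -1.87 for nad3, -1.78 for rps12, -1.33 for nad9, -1.05 for cox3 and -0.98 for atp4, and the median of the mitochondrial group was -0.75.

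The lower response of mitochondrial genes in bzip60-2 at V5 was weighed against 2 technical explanations. Carry-over of organelle RNA through poly(A) selection, alike for both organelles, would lower the plastid genes too, but their median interaction was 0.186 (median absolute deviation 0.258) against -0.754. The scale of the libraries is argued against by 12 of 21 genes that had a lower response after size-factor scaling as well. The mutant's high level at 31 °C, with a sum of 152 FPKM (91.0 without rps12) against 53.7 in W22 (31.98), is itself part of this difference, so it was not counted as an explanation, and no biological explanation was tested. Carry-over that differs between the organelles, and the chambers, were not tested.

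The departure of replicate 3 of W22 at V4 and 37 °C was weighed against 3 technical explanations. A wrong label is argued against by its mean correlation with its own group, 0.985, which was above that with any other group (at most 0.974). RNA of the mutant mixed into it is argued against by a median share of -0.178% over 18 genes at least 10-fold higher in the mutant (from -68.8 to 45.1%). A difference in how 2 sets of libraries were made or sequenced may account for it: across 6238 genes its departure correlated with 9 comparisons of other libraries across the sets (median r 0.509, 0.261 to 0.610), and hardly with 26 within a set (median absolute r 0.0365, highest 0.0760), though genes are not independent replicates. A state of the plants that parts the same libraries is as open, and no biological explanation was tested.

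Other splits gave fewer genes than the real ones in the remaining tests with 100 splits. In each, 1 of 100, the real one, gave as many. A random assignment of libraries or group means is argued against by this measure. Replicates of a group were so alike that splits of libraries cannot decide on chance between plants or chamber pairs. With group means as the replicates, 1704 genes differed between genotypes at V5. The real and the highest other counts were 15040 and 9970 (W22 V4), 18470 and 13610 (W22 V5), 16452 and 12023 (bzip60-2 V4) and 16591 and 13642 (bzip60-2 V5) in the temperature F tests. They were 16096 and 12316 (V4) and 16842 and 6683 (V5) between genotypes, and 18586 and 16859 (W22) and 18732 and 13390 (bzip60-2) between stages. They were 11035 and 6243 over 8 pairs of group means, and 3601 and 17 for the slope. Contrasts of 3 against 3 libraries have 10 splits, too few for a share under 0.05; real counts ran from 5832 to 15401 and the highest others from 0 to 423.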

How the results depend on the processing

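Chosen after the data were seen were the set term, group means as replicates, pairs or groups within a set, and all results from group means; the other alternatives were planned. Counts stayed within 1.5 times the reported ones with a pseudocount of 0.1, no filter, array weights, models of 24 libraries and each library left out, and with 1 group left out of the slope (2418 to 4450) or 1 of the 8 pairs (9071 to 11178). Quantile normalization gave 7509 genes between genotypes at V4 and 31 °C (11337 reported) and 4636 over 8 pairs of group means (11035 reported), and size-factor scaling 5475 over the pairs. With the set term, bzip60-2 at V4 had 4508 genes at 33 °C (10318), 4743 at 35 °C (10417) and 7019 at 37 °C (12590). The genotypes at V4 had 9421 (16096), with 3865 at 33 °C (9846) and 4849 at 35 °C (10833), and the stages in W22 had 11224 (18586). Simulated genes that differ between the sets alone were called without the term, and the term's own error also lowers counts. Zm00001d033132 and Zm00001d033136 reversed to -0.15 in the V4 interaction. Group means as replicates gave 5904 and 1704 genes between genotypes at V4 and V5 (16842 at V5), and 6229 and 8859 between stages in W22 and bzip60-2 (18732 in bzip60-2), and the 5 pairs within a set 5929, with fewer units in each. For quantile normalization and scaling the cause was not tested.

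Of named genes and groups, leaving out a library or group ended the call in 135 of 1730 values, with no change of direction. The set term ended 10, 2 of them with the reversal above. It also ended calls that are not in this tally. At 37 against 31 °C in bzip60-2 at V4 these included nad3, atp4, rps2B, atpF, rpl2 and atpH. There Zm00001d033133 went from 7.14 to -1.13 (adjusted p = 0.654 in the limma model with the term). In the tally, size-factor scaling ended 10, quantile normalization 12, no filter 10, the pseudocount 5, array weights 4, the 24 libraries 4, an estimated correlation 3, the 5 pairs within a set 10, and the groups within a set 2. A replicate block gave, for example, 10533 genes for W22 V4 at 37 °C (10560 without it), and no call of a gene or group changed with it. Same-numbered libraries did not deviate together (mean r -0.00195, from -0.0941 to 0.0960; 15 of 48 correlated best with their own number), so the numbers were not taken as pairs. The 22 gene lists were not run, for want of names. Depth in reads is unknown, and genes near 0 FPKM, clpP and rpl16 among them, are the least certain.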

Other observations

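In this part, the placement of differences along the identifiers, the families of organelle genes and the fits to group means were chosen after the result was seen. Transcripts of the 21 mitochondrial genes summed to 23.6 ± 2.41, 26.9 ± 3.48, 78.0 ± 12.2 and 70.5 ± 3.09 FPKM at 31, 33, 35 and 37 °C in W22 at V4 (mean ± SD, n = 3), so the level at 35 °C was near that at 37 °C. In W22 at V5 the sums were 53.7 ± 4.32, 118 ± 5.05, 115 ± 4.59 and 123.2 ± 1.58, and the level was already high at 33 °C. In bzip60-2 they were 35.9 ± 3.59, 40.2 ± 0.821, 68.2 ± 9.11 and 84.6 ± 7.14 at V4, and 152 ± 5.67, 151 ± 3.88, 146 ± 13.8 and 125 ± 1.82 at V5. These sums were not tested, and rps12 held much of them: without it the sums at 31 and 37 °C were 11.0 and 34.2 FPKM in W22 at V4, 31.98 and 80.5 in W22 at V5, 19.6 and 50.8 in bzip60-2 at V4, and 91.0 and 91.4 in bzip60-2 at V5.

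By the slope over temperature, 2 of 9 plastid ribosomal protein genes and 1 of 8 NDH complex genes rose and 0 fell, and 1 of 3 photosystem genes rose and 2 fell. The photosystem I genes psaA and psaB are among these, and the call for psaA was lost without W22 V4 at 31 °C, bzip60-2 V4 at 37 °C, W22 V5 at 31 °C, or bzip60-2 V5 at 31 or 37 °C (adjusted p up to 0.0924). Mitochondrial rps7, a ribosomal protein gene, had a fitted log2 change of 1.19 (adjusted p = 0.00558) from 31 to 37 °C. A straight line left 52.2% of the temperature sum of squares in W22 V4, 70.6% in W22 V5, 43.3% in bzip60-2 V4 and 49.1% in bzip60-2 V5. At any size of change, 1620 genes rose and 1481 fell at 37 against 31 °C in all 4 series, where independent lists would share 92.9 and 71.3.

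Strong differences between the genotypes over 8 pairs of group means (past the threshold and at least 2-fold from the median of the nuclear genes) lay close together in the order of the identifiers. Of 305 such genes among 20570, 23 fell between Zm00001d044945 and Zm00001d045433, a run of 200 identifiers where 2.97 would fall by chance, with 11 higher in the mutant and Zm00001d045054 (log2 difference 3.24) and Zm00001d045322 (-3.74) among them. Chance placement is argued against by a permutation p of 0.0001, the smallest that 10000 placements can give (highest count 15). Of the genes most different between stages, a set of the same size, 2 fell in the run, 0.674 of the average. Neighbours that move together are argued against by this for the stage contrast alone, and other contrasts were not tested. A chromosome segment of another origin in the mutant line may account for it, since the differences varied less over the 8 pairs (median ratio of SD to size 0.228) than in 266 strong genes outside this and a second run (0.421, two-sided permutation p = 0.0074). The second run, from Zm00001d048533 to Zm00001d049068, held 16 such genes (permutation p 0.0001) and did not show this (0.420, p = 0.991), so its cause is open. Size-factor scaling left 23 genes in the first run (22 shared), the 5 pairs within a library set gave 23 of 323 there, and whether identifiers follow the chromosomes was not checked.

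A hypothesis from these data is that bzip60-2 lies toward V5 along the difference between V4 and V5. Genotype and stage differences taken from separate libraries of 1 library set correlated across genes at a median r of 0.320 within classes of mean expression (0.199 to 0.607), and at 0.416 and 0.329 over all genes for 2 divisions of the temperatures (Spearman 0.432 and 0.344). Within 1 set, the genotype difference was bzip60-2 minus W22 at V5. The stage difference was V5 minus V4 in bzip60-2, at other temperatures. Both thus start from bzip60-2 at V5, so anything particular to that series also makes r positive. The correlation therefore cannot decide on the hypothesis. The values may also reflect a property of the samples that genotype and stage share, such as the share of FPKM in a few genes, and genes are not independent replicates.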
